A study of Mus musculus with 2 samples.

How the data were processed

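RNA sequencing was done on 2 samples of mouse embryonic heart, replicate 1 and replicate 2, taken at embryonic day 12.5 from a mixed C57BL/6 x 129S6 background. Per the labels' protocols, total RNA was extracted with Trizol, libraries were made with the Illumina TruSeq RNA v2 kit, and products were selected by size. Nothing in the sources used here says whether the samples came from separate embryos, pools or litters. The spread between them may therefore be technical. Both samples form a single group, so no comparison between conditions was made.

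The authors deposited 1 table per sample with an FPKM value (fragments per kilobase of transcript scaled to the mapped fragments of the library) for each gene. Per the submitters' processing notes, GSNAP, Cufflinks and Cuffnorm were used and the builds mm9 and hg19 were named, with no versions. The gene annotation, the strand setting and the handling of reads with several matches are not given in the sources used here. Gene positions in the files are on mm9: the last gene of chromosome 1 ends at 197054592, beyond the last gene end of 195291439 in the GRCm38 annotation used here. Coordinates printed here are those of the files. Each table holds 37620 gene rows with 22 gene types. Rows with the same symbol were summed, which gave 34236 symbols, of which 346 had more than 1 row, U6 alone having 936.

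Raw counts were not used here, so absolute depth is unknown and no count model was fitted. Relative depth was read from genes under 0.1 FPKM in both libraries, where many values stand for single fragments. Among 2881 such genes, 479 had a ratio of replicate 2 to replicate 1 within 0.05 log2 units of 1.32. A fragment was thus worth 1.32 times as much in replicate 2, and replicate 1 was deeper by that factor. No interval for counting error can be given.

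Log2 values were taken after adding a pseudocount of 1 FPKM, which understates the differences of low genes. A gene was called detected at 1 FPKM or more. Differences between the libraries were counted by a rule of size, 2-fold or more at a mean of 5 FPKM or more. With 2 libraries in 1 group, the smallest two-sided p of an exact sign-flip test is 0.5, so no p-value is attached to them. Gene lists (41) and pairs of related genes (32) were fixed before the data were examined. For each list, the median log2(FPKM + 1) was ranked among the medians of 10000 random lists of the same size, drawn from genes above 0 FPKM in at least 1 library. Lists above the 97.5th or below the 2.5th percentile were said to stand apart. The median difference of a list between the libraries was ranked among 10000 random lists matched on expression in 10 bins, over members with a mean of 1 FPKM or more. The log2 ratio of each pair was set against the 95th percentile of the differences of single genes between the libraries. Of 620 listed symbols, 613 were found as written, 5 through their gene ID under an older symbol, and 2 (Ahsp and Zac1) were not found. In the gene name table, 32897 gene IDs matched.

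Genes are named by a rule fixed before the data were examined. It takes the 25 genes with the highest mean FPKM, the 4 highest members of each list and up to 3 of its lowest members under 1 FPKM. It also takes both genes of each pair, the 8 genes per direction that differed most between the libraries at a mean of 5 FPKM or more, and the sex-linked list. The lists of cardiac transcription factors, conduction system, epicardium and skeletal muscle may be named in full. Some genes that the rule takes are not reported here. Genes outside the rule are marked where they appear as chosen after their values were seen.

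The alternatives tried were another pseudocount, detection limit and filter, another set of genes for the random lists, rescaling of the libraries, the highest row per symbol, and each library alone. For list levels set against genes with a mean of 1 FPKM or more, list members under that mean were left out too. Corrections for transcript length and GC content, a restriction to protein-coding genes, the removal of members at 0 and, for the levels of gene lists, the highest row per symbol were added after the data were examined. Transcript lengths, GC content and near-identical copies came from GENCODE M21 transcripts on GRCm38, matched by gene. Copies were sought with BLAST 2.17.0, as matches to another gene at 98% identity or more over at least 75 bases. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

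The steps were tested on simulated data. A depth ratio made 1.5 was found as 1.47. For replicate 2 against replicate 1, the 2-fold rule found 10% of the genes made exactly 2-fold higher and 100% of those made 3-fold higher among 8920 genes, with 0 unchanged genes called. Fragments were drawn with counting noise alone at an assumed depth. The 0 therefore does not measure the rate of false calls in the real libraries. Random lists of 15 fell outside the central range in 6% of cases for levels and 3.75% for differences. Lists raised by 3 log2 units in level were found in 93% of cases, and lists raised by 0.15 log2 units between the libraries in 100%.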

Results

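Gene expression was measured by RNA sequencing in 2 libraries of mouse heart at embryonic day 12.5, a stage at which the chambers have formed and the valves and septa are still developing. The libraries form 1 group, and the data describe which genes the heart RNA held, at what level, and how closely the libraries matched. Values are mean FPKM ± SD over the 2 libraries (n = 2) unless a library is named. The summed FPKM was 388230 in replicate 1 and 382561 in replicate 2. Absolute depth is unknown, and replicate 1 was 1.32 times as deep as replicate 2. The sources used here do not say whether the samples came from separate embryos, so the spread may be technical.

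The most abundant transcript was Hbb-y, an embryonic beta-like globin of primitive red cells, at 15962 ± 813 FPKM (chromosome 7, 111000259 to 111001754, mm9). Genes of the mitochondrial genome followed, with mt-Co1 at 9092 ± 637, mt-Nd1 at 6068 ± 453 and mt-Cytb at 5710 ± 619 FPKM. The alpha globin Hba-a1 stood at 4435 ± 134 FPKM and Actc1, the cardiac alpha actin, at 4314 ± 98.4 FPKM (chromosome 2, 113873018 to 113879284). H19, an imprinted noncoding RNA, reached 3505 ± 4.56 FPKM, and its neighbour Igf2, a fetal growth factor, 1786 ± 23.0 FPKM. Myl2, the ventricular regulatory myosin light chain, was at 3268 ± 115 FPKM and the elongation factor Eef1a1 at 3186 ± 54.4 FPKM. Among the 25 highest genes were also Myl7, Myl4, Myl3, Tnnt2, Tpm1 and Tnnc1 of the sarcomere, the natriuretic peptide gene Nppa, the imprinted gene Mest, Atp5b of the ATP synthase and Rps15 of the ribosome. The 10 highest genes held 15.2% of the summed FPKM in replicate 1 and 15.7% in replicate 2, and the 100 highest held 32.7% and 33.3%.

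**Figure D1:**
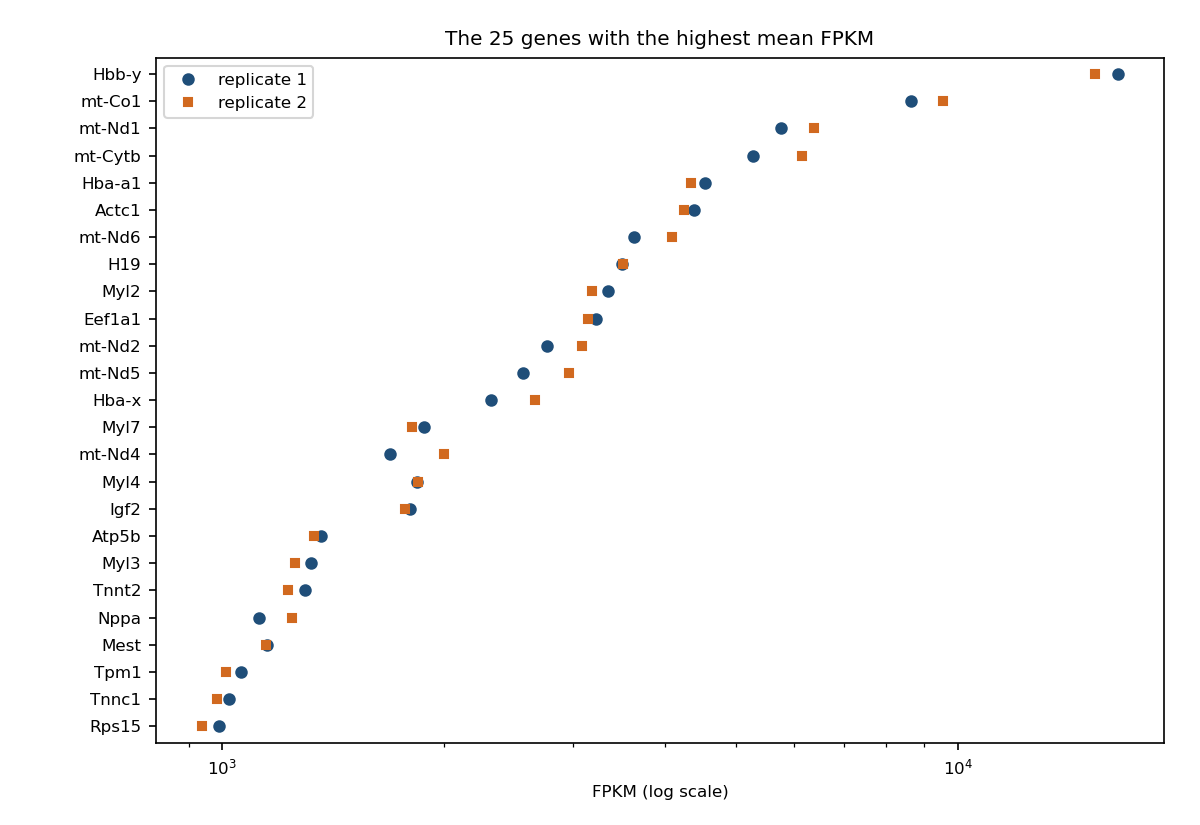
FPKM on a log axis of the 25 genes with the highest mean, with a circle for replicate 1 and a square for replicate 2. Hbb-y lies highest, at 16536 and 15387 FPKM.

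In both libraries 12381 genes reached 1 FPKM, against 12557 in replicate 1 and 12693 in replicate 2. Of these 12381 genes, 11650 were protein-coding, which is 52.4% of the 22218 protein-coding symbols, 450 were pseudogenes, 147 were lincRNAs and 69 were antisense genes. A further 488 genes reached 1 FPKM in exactly 1 library, and 11479 were listed at 0 in both. A value listed at 0 can be a failed estimate and does not show that the transcript was absent.

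Genes of the contractile apparatus were among the highest of all lists. All 24 sarcomere genes reached 1 FPKM in both libraries, with a median of 351 FPKM (percentile 100 among random lists), and they held 5.11% of the summed FPKM in replicate 1 and 4.96% in replicate 2. After Actc1 and Myl2 came the light chains Myl7 at 1847 ± 50.2 and Myl4 at 1843 ± 7.74 FPKM. The list of calcium handling genes and ion channels had 20 of 20 members detected (percentile 99.98), led by the calcium pump inhibitor Pln at 372 ± 5.34 FPKM, the calcium pump Atp2a2 at 276 ± 24.4, the sodium-calcium exchanger Slc8a1 at 112 ± 10.5 and the junction protein Jph2 at 64.1 ± 1.09 FPKM.

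Of 24 cardiac transcription factors, 23 were detected in both libraries (percentile 99.99, and 96.9, no longer apart, against genes with a mean of 1 FPKM or more). Here and below, members under that mean were left out when a list was set against such genes. Gata4 was at 96.5 ± 0.715 FPKM, Tbx20 at 91.9 ± 6.23, Nkx2-5 at 54.1 ± 0.950 and Gata6 at 48.0 ± 2.03 FPKM. The second heart field regulator Isl1 was at 2.26 ± 0.204 FPKM, and Tbx1, a gene of the pharyngeal region, was the member under the limit at 0.151 ± 0.0417 FPKM. The congenital heart disease list, which shares Gata4, Tbx20 and Nkx2-5 with the former and has Eln among its 4 highest members at 94.9 ± 15.6 FPKM, had 21 of 29 measured members detected and did not stand apart (percentile 90.3).

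Atrial and ventricular markers were both present. The atrial list (12 of 12 detected, percentile 99.86) was led by Myl7, Myl4, Nppa at 1182 ± 87.4 FPKM and the gap junction gene Gja5 at 66.0 ± 2.98 FPKM. The ventricular list (12 of 12, percentile 100) was led by Myl2, Myl3 at 1288 ± 45.4, Myh7 at 446 ± 59.0 and Pln. Trabecular genes (10 of 10, percentile 99.49) included Cited1 at 241 ± 2.95 and Nppb at 86.0 ± 5.22 FPKM. Compact layer genes (9 of 9, percentile 99.69) included the cyclins Ccnd2 at 81.5 ± 3.42 and Ccnd1 at 39.9 ± 0.468 FPKM and the Notch target Hey2 at 40.6 ± 3.27 FPKM. Set against genes with a mean of 1 FPKM or more, atrial (96.7), trabecular (91.4) and compact (95.9) markers no longer stood apart. The list of the conduction system and atrioventricular canal had 14 of 15 members detected without standing apart (percentile 86.6, and 13.8 against genes with a mean of 1 FPKM or more). Among its highest members were the connexin Gjc1 at 31.1 ± 0.897, Bmp4 at 21.7 ± 0.571 and Shox2 at 10.01 ± 0.675 FPKM. The pacemaker channel Hcn4 was at 8.68 ± 0.349 FPKM and Cntn2, a marker of Purkinje cells, at 0.0530 ± 0.0104 FPKM. In the second heart field and outflow list 7 of 14 genes were detected (percentile 41.2), with Hand2 at 42.7 ± 0.570, Mef2c at 19.8 ± 1.38 and Tlx1 at 0.0986 ± 0.00402 FPKM.

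Genes listed for other cell types of the heart were also detected, though members of a list can be expressed in more than 1 cell type. Endothelial and endocardial genes stood apart (19 of 20 detected, percentile 100), with Egfl7 at 70.1 ± 1.29, Eng at 63.3 ± 2.95, Plvap at 44.3 ± 0.330 and Cdh5 at 37.3 ± 2.54 FPKM. Matrix genes of fibroblasts did so too (16 of 16, percentile 100), with Sparc at 517 ± 7.87, Fstl1 at 282 ± 5.37, Col3a1 at 189 ± 18.5 and Postn at 113 ± 4.02 FPKM. Cushion and valve mesenchyme (18 of 18, percentile 98.4) shares Col3a1, Postn and Tbx20 with other lists, and against genes with a mean of 1 FPKM or more it lay at percentile 53.1. Smooth muscle genes (10 of 12, percentile 99.92) were led by Acta2 at 393 ± 10.7 and the intermediate filament gene Des at 182 ± 2.64 FPKM, while Myh11, the myosin of mature smooth muscle, stayed at 0.496 ± 0.106 FPKM. Smooth muscle lay at percentile 97.41 against genes with a mean of 1 FPKM or more, just inside the range. All 14 epicardial genes were detected without the list standing apart (percentile 91.9, and 22.9 against genes with a mean of 1 FPKM or more). Upk3b was at 63.1 ± 0.434, Tcf21 at 32.1 ± 0.610, Aldh1a2 at 19.8 ± 0.871, Tbx18 at 19.7 ± 0.962 and Wt1 at 13.4 ± 0.270 FPKM. Of 11 neural crest and Schwann precursor genes 5 were detected (percentile 6.66), among them Ednrb at 33.9 ± 1.19 and Ets1 at 23.5 ± 0.361 FPKM, genes that endothelium also expresses, whereas Foxd3 was at 0.0375 ± 0.0272 FPKM.

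Blood cell lists differed widely. Erythroid genes stood far above random lists (18 of 19 measured at 1 FPKM in both libraries, percentile 100) and held 6.46% of the summed FPKM in replicate 1 and 6.31% in replicate 2. Macrophage genes (12 of 14) did not stand apart (percentile 65.2). Those with a mean of 1 FPKM or more lay below the range among genes at that mean, at percentile 0.67. The highest was Lyz2 at 21.7 ± 0.805 FPKM. Megakaryocyte and platelet genes (6 of 10, percentile 49.5, and 12.2 against genes with a mean of 1 FPKM or more) were led by the platelet chemokine Pf4 at 12.7 ± 1.60 FPKM. No lymphocyte gene reached 1 FPKM in both libraries (0 of 12, percentile 0). The T cell kinase Lck was highest there at 1.01 ± 0.0208 FPKM, and Cd3d and Ms4a1 were listed at 0.

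Lists of neighbouring tissues gave mixed results. Hepatocyte genes had 1 of 14 members detected (percentile 1.43, and 2.71 in replicate 1 alone). Afp, at 1.17 ± 0.446 FPKM, and Alb, at 0.849 ± 0.384 FPKM, did not reach 1 FPKM in both libraries. The detected member was another gene, not reported here. Lung and foregut epithelium had 4 of 13 (percentile 0.55), of which Id2 at 117 ± 1.53 FPKM is widely expressed, and the detected members lay at percentile 26.45 among genes with a mean of 1 FPKM or more, while Foxa1 was at 0.00300 ± 0.00425 FPKM. Thymus and pharyngeal pouch had 0 of 10 (percentile 0, and 4.165 without its members at 0), with Foxn1, Gcm2 and Pth listed at 0. Among skeletal muscle genes 4 of 14 were detected (percentile 0.75), and these 4 alone lay at percentile 97.6, above the range, against genes with a mean of 1 FPKM or more. These were Tnnt1 at 174 ± 18.9, Acta1 at 91.4 ± 2.95, Tnni2 at 16.2 ± 3.25 and Tnnt3 at 2.90 ± 0.225 FPKM. The muscle regulators Myod1 and Pax7 were at 0.105 ± 0.0269 and 0.00579 ± 0.00364 FPKM. Neuronal genes did not stand apart (6 of 14, percentile 19.1), with Gap43 at 13.8 ± 0.936 FPKM. Those with a mean of 1 FPKM or more lay below the range among genes at that mean, at percentile 0.33. Of 29 Hox genes none reached 1 FPKM in both libraries (percentile 0.015), and the highest was Hoxa5 at 0.815 ± 0.308 FPKM. In the sex-linked list Xist was at 53.6 ± 1.67 FPKM, and the Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d lay between 0.0273 ± 0.0267 and 0.00170 ± 0.00240 FPKM.

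Cell cycle and metabolic genes were high. All 27 proliferation genes were detected (percentile 100), with Ube2c at 102 ± 4.10, Cdk1 at 99.3 ± 2.44 and Pcna at 93.1 ± 3.08 FPKM. Glycolysis (18 of 18, percentile 100) was led by Aldoa at 780 ± 36.1, Ldha at 732 ± 48.7, Pkm2 at 531 ± 25.4 and Tpi1 at 429 ± 21.03 FPKM. Fatty acid oxidation (19 of 20, percentile 100) was led by Etfb at 131 ± 3.90 and Acadl at 104 ± 4.25 FPKM, and the regulator Ppara was at 0.872 ± 0.292 FPKM. The nuclear genes of oxidative phosphorylation (25 of 25, percentile 100) included Atp5b at 1347 ± 23.0, Atp5a1 at 732 ± 5.44 and Cox4i1 at 626 ± 26.8 FPKM. Hypoxia response genes (16 of 16, percentile 100) included Mif at 475 ± 14.3 FPKM besides Ldha and Slc2a1. Ribosomal protein genes (30 of 30, percentile 100) included Rpl32 at 937 ± 28.5 FPKM, and Rps15 was not among the 30. Of 13 mitochondrially encoded genes 12 were detected in both libraries (percentile 100), and the list held 7.82% of the summed FPKM in replicate 1 and 8.95% in replicate 2. Several of them, like some ribosomal protein genes and Gapdh, share sequence with near-identical copies, and their levels are uncertain. Imprinted genes (16 of 17, percentile 100) had Grb10 at 319 ± 17.2 FPKM after H19, Igf2 and Mest. Immediate early and heat shock genes (16 of 21, percentile 97.9) were led by Jun at 25.9 ± 0.313 FPKM, with Fosb at 0.184 ± 0.00571 FPKM, and lay at percentile 70.3 against genes with a mean of 1 FPKM or more. Replication-dependent histone genes lay just below the lower limit (2 of 18, percentile 2.49, and 4.68 in replicate 1 alone). Their transcripts lack poly(A) tails, and the highest was Hist1h1c at 9.89 ± 0.710 FPKM.

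Among signalling lists, BMP and TGF-beta (22 of 22, percentile 99.98) and FGF, neuregulin and IGF (17 of 20, percentile 99.3) stood apart. The former was led by the BMP targets Id2 and Id3, the latter at 93.3 ± 0.387 FPKM, and the other list by Igf2 and Igfbp5 at 194 ± 10.7 FPKM. Notch (16 of 16, percentile 81.2) and Wnt (20 of 21, percentile 96.2) did not, with Hes1 at 14.0 ± 0.922 FPKM and Ctnnb1 at 235 ± 8.44 FPKM among their highest members. In all, 23 of the 41 lists stood apart above random lists and 8 below them. Against genes with a mean of 1 FPKM or more, BMP and TGF-beta lay at percentile 97.39 and FGF, neuregulin and IGF at 71.8, neither apart, while Notch lay at 3.43 and Wnt at 28.9. Of the 35 lists that could be set against such genes, 15 lay above the range and 2, macrophage and neuron, below it. The 15 include skeletal muscle (97.6), by construction, since only its 4 detected members were left.

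**Figure D2:**
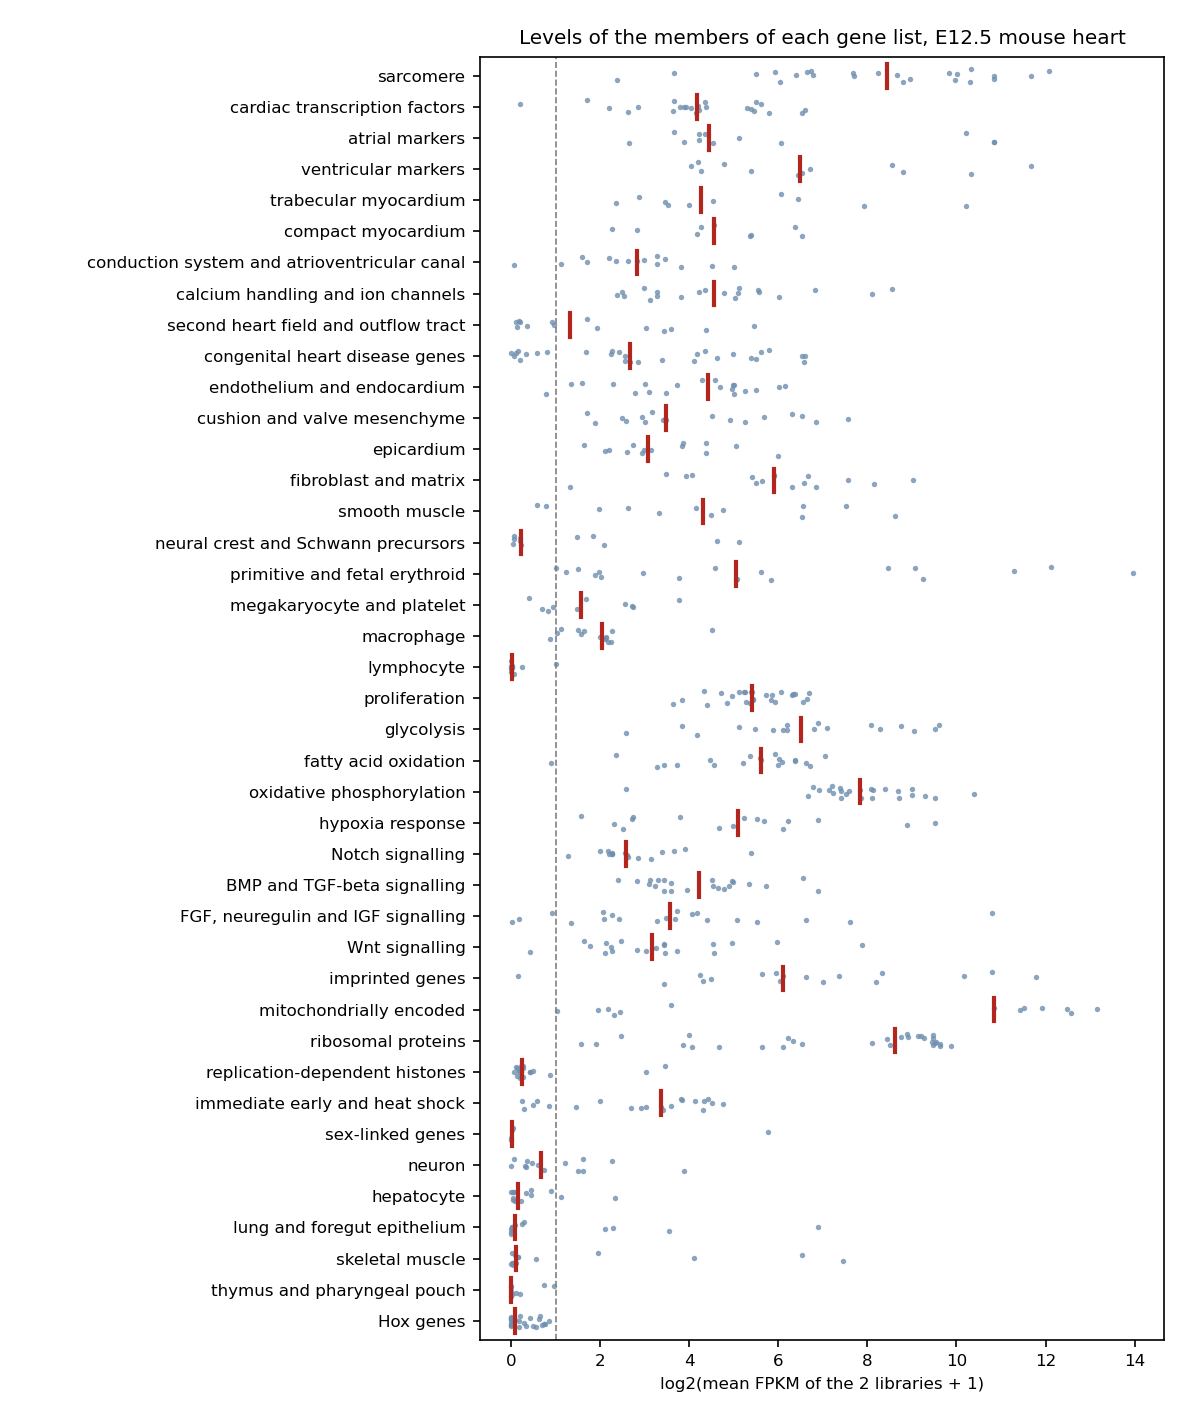
Each point is a gene of the named list, placed by log2(mean FPKM + 1), the red bar is the list's median and the dashed line marks 1 FPKM. The sarcomere list has its median at 8.44 and the lymphocyte list at 0.0164.

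Pairs of related genes were compared by their FPKM. For all 32 pairs the size of the mean log2 ratio, in either direction, was larger than 0.32, the 95th percentile of differences of single genes between the libraries. That limit covers the spread between the libraries only, not errors between genes that both libraries share, such as reads lost to copies. Myh7, the slow beta myosin heavy chain, exceeded Myh6, the alpha chain, at 446 ± 59.0 against 208 ± 20.1 FPKM (log2 ratio 1.09 ± 0.05). The fetal troponin Tnni1 exceeded the adult Tnni3, at 917 ± 16.1 against 403 ± 16.4 FPKM (1.19 ± 0.03). Actc1 was 46.7 times Acta1 on the pseudocount scale (5.55 ± 0.08), and Tnnt2 was 7.23 times Tnnt1. Myl7 was lower than Myl2 (-0.82 ± 0.01), and Myl4 was higher than Myl3 (0.52 ± 0.06). Tpm1 exceeded Tpm2 (4.12 ± 0.09), Mybpc3 exceeded Mybpc1 (6.77 ± 0.03) and Nppa exceeded Nppb (3.76 ± 0.19).

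In calcium handling, Atp2a2 was at 276 FPKM and Atp2a1 at 1.28 ± 0.252 FPKM, and Ryr2, at 7.66 ± 1.24 FPKM, exceeded Ryr1, at 0.0254 ± 0.00256 FPKM (log2 ratio 3.07 ± 0.21, and 5.94 with a pseudocount of 0.1). Casq1, the calsequestrin known from fast skeletal muscle, was higher than the cardiac Casq2, at 95.5 ± 12.5 against 45.9 ± 3.54 FPKM. Cacna1c exceeded Cacna1d (1.39 ± 0.08), Hcn4 exceeded Hcn2, at 0.174 ± 0.00737 FPKM (3.04 ± 0.06, and 5.0 with a pseudocount of 0.1), and Gja1 exceeded Gja5 (0.64 ± 0.11). Of the transcription factors, Gata4 exceeded Gata6 (0.99 ± 0.07), Hand2 exceeded Hand1 (1.41 ± 0.04) and Hey2 exceeded Hey1 (1.72 ± 0.14). Tbx2 exceeded Tbx3 by 0.44 ± 0.18, and in replicate 1 alone by 0.31, within the spread of single genes.

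In metabolism, the muscle carnitine palmitoyltransferase Cpt1b exceeded the liver form Cpt1a, at 60.1 ± 2.18 against 9.85 ± 0.618 FPKM. The glucose transporter Slc2a1 was at 117 ± 3.01 FPKM and the insulin-responsive Slc2a4 at 12.6 ± 0.0485 FPKM. Ldha exceeded Ldhb (1.76 ± 0.03), Hk1 exceeded Hk2 (2.36 ± 0.19) and the brain-type creatine kinase Ckb exceeded the muscle-type Ckm (1.85 ± 0.26). The widely expressed cytochrome oxidase forms exceeded the heart and muscle forms, with Cox6a1 over Cox6a2 at 1.41 ± 0.01, Cox7a2 over Cox7a1 at 1.22 ± 0.00017 and Cox8a over Cox8b at 3.92 ± 0.03. Slc25a4 exceeded Slc25a5 (0.61 ± 0.01) and Fabp3 exceeded Fabp4 (3.60 ± 0.32). Among globins, Hbb-y was 26.6 times Hbb-bh1 (605 ± 117 FPKM) and 29.8 times Hbb-b1 (536 ± 57.9 FPKM), and the embryonic Hba-x, at 2490 ± 242 FPKM, was lower than Hba-a1 (-0.84 ± 0.18). Hba-a1 has a near-identical copy in Hba-a2, as Hbb-b1 has in Hbb-b2, and reads may be split between them, so these globin ratios are uncertain.

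**Figure D3:**
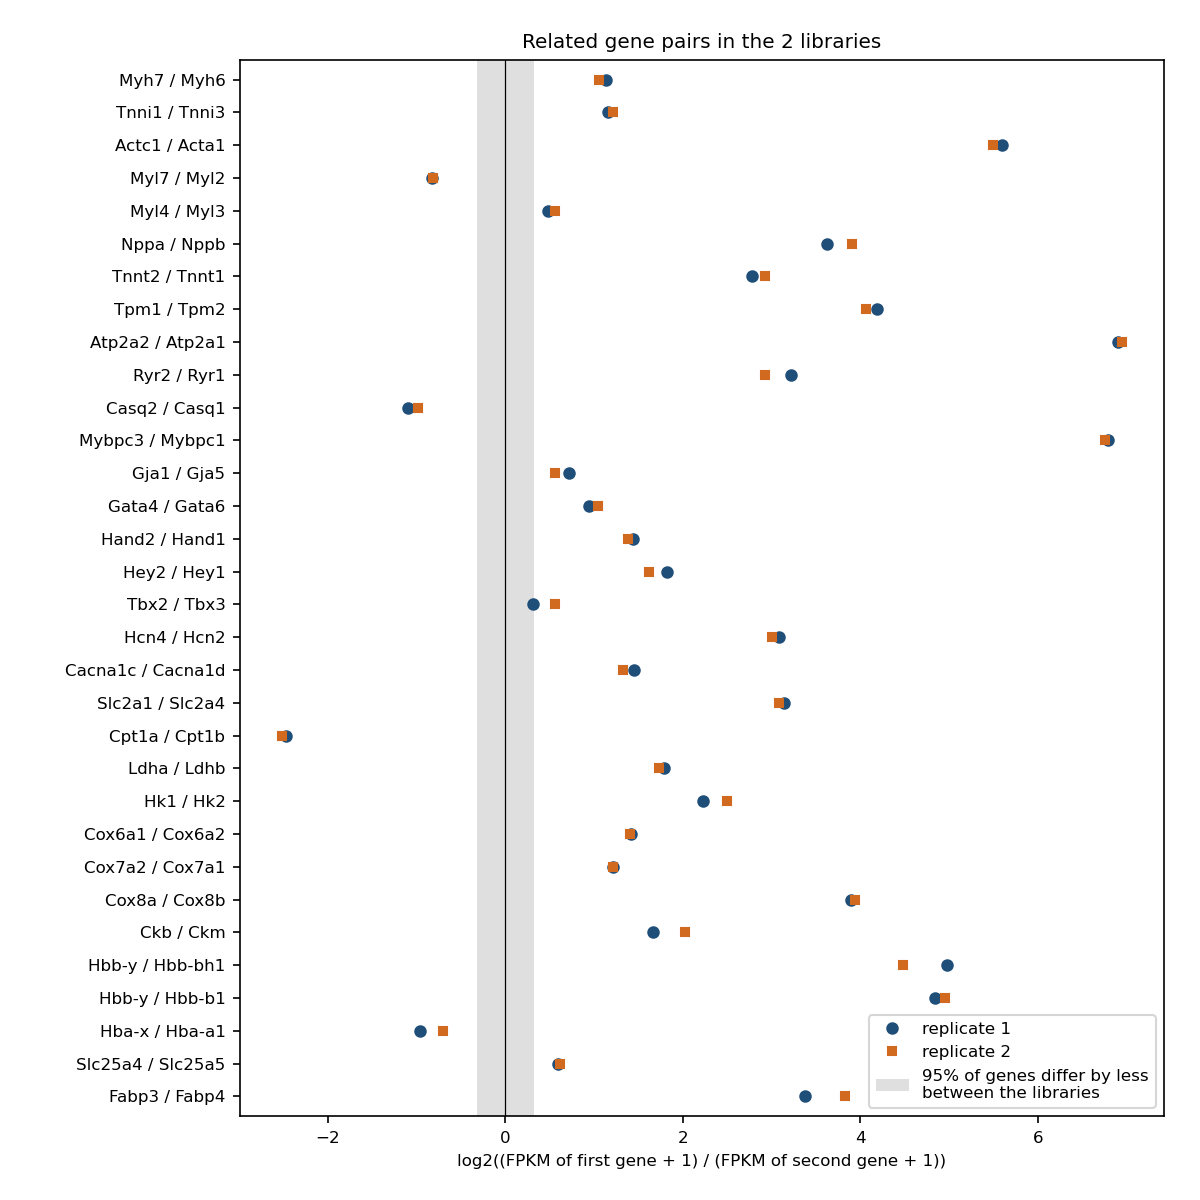
Log2 ratio of the first to the second gene of each pair, with a circle for replicate 1 and a square for replicate 2. The grey band spans ±0.32, within which 95% of single genes with a mean of 1 FPKM or more differed between the libraries, and Tbx2 over Tbx3 in replicate 1 lies inside it.

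The libraries matched closely across genes. Pearson's r of log2(FPKM + 1) was 0.997 and Spearman's rho 0.970 across 34236 symbols, which are not independent replicates. Of genes with a mean of 1 FPKM or more, 95% differed by less than 0.32 log2 units. The central 68% of log2 differences had a half-width of 0.23 for genes between 1 and 2 FPKM, 0.06 between 50 and 100 FPKM and 0.05 from 300 FPKM upward. At 5 FPKM or more, 31 of 8924 genes differed 2-fold or more, 23 higher in replicate 2 and 8 higher in replicate 1. The count was 93 at a mean of 1 FPKM or more, 64 of them higher in replicate 2, and 105 with no filter, 75 of them higher in replicate 2. Of the 31, 6 were protein-coding, and the rest were pseudogenes and genes of small or ribosomal RNA. Higher in replicate 2 were the pseudogenes Gm13343, Gm15536, Gm13443 and Gm14539, SNORA1, U1, Rps18 (98.8 against 451 FPKM) and Rpl15 (39.8 against 95.2 FPKM). Higher in replicate 1 were n-R5s193, Rps2-ps13, n-R5s192, U6 (598 against 143 FPKM), n-R5-8s1, snoU97, SNORA18 and H2-D1, a major histocompatibility gene (15.2 against 6.62 FPKM). H2-D1 lies on chromosome 17 (35399675 to 35404444) near other genes that differed between the libraries. Pseudogenes, ribosomal protein genes and small RNA genes belong to families that can have near-identical copies, and how reads with several matches were counted is not given, so their values are uncertain.

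Between the libraries, 14 of 35 gene lists had a median difference outside the central range of matched random lists. By chance 1.75 would be expected for lists of unrelated genes. Genes of a list can vary together and lists share members, so the 14 are not independent differences. Mitochondrially encoded genes were higher in replicate 2 (median log2 difference 0.17, 12 of 13 members), as were erythroid genes (0.09, 11 of 19) and atrial markers (0.06, 10 of 12). The summed erythroid FPKM, most of it Hbb-y, went the other way. Lower in replicate 2 were megakaryocyte genes (-0.41, 6 of 6 members), macrophage genes (-0.15, 11 of 13), glycolysis (-0.10, 18 of 18), sarcomere (-0.08, 22 of 24), endothelium (-0.09, 16 of 19) and Notch genes (-0.12, 11 of 16). Lower too were fibroblast and matrix (-0.11, 15 of 16), second heart field (-0.12, but only 4 of 7), calcium handling (-0.10, 17 of 20), FGF, neuregulin and IGF (-0.10, 14 of 17) and congenital heart disease genes (-0.08, 17 of 21). Longer transcripts were lower in replicate 2, with a median log2 difference of -0.10 in the tenth of genes with the longest transcripts and -0.03 in the shortest. After correction for length, the 5 last-named lists came inside the random range and the 6 named before them stayed below it. The same correction, chosen after the data were examined, put ventricular markers (percentile 0.97) and hypoxia response (0.11) below the range and trabecular genes (98.9) above it. These differences compare 2 libraries and have no replicate check.

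**Figure D4:**
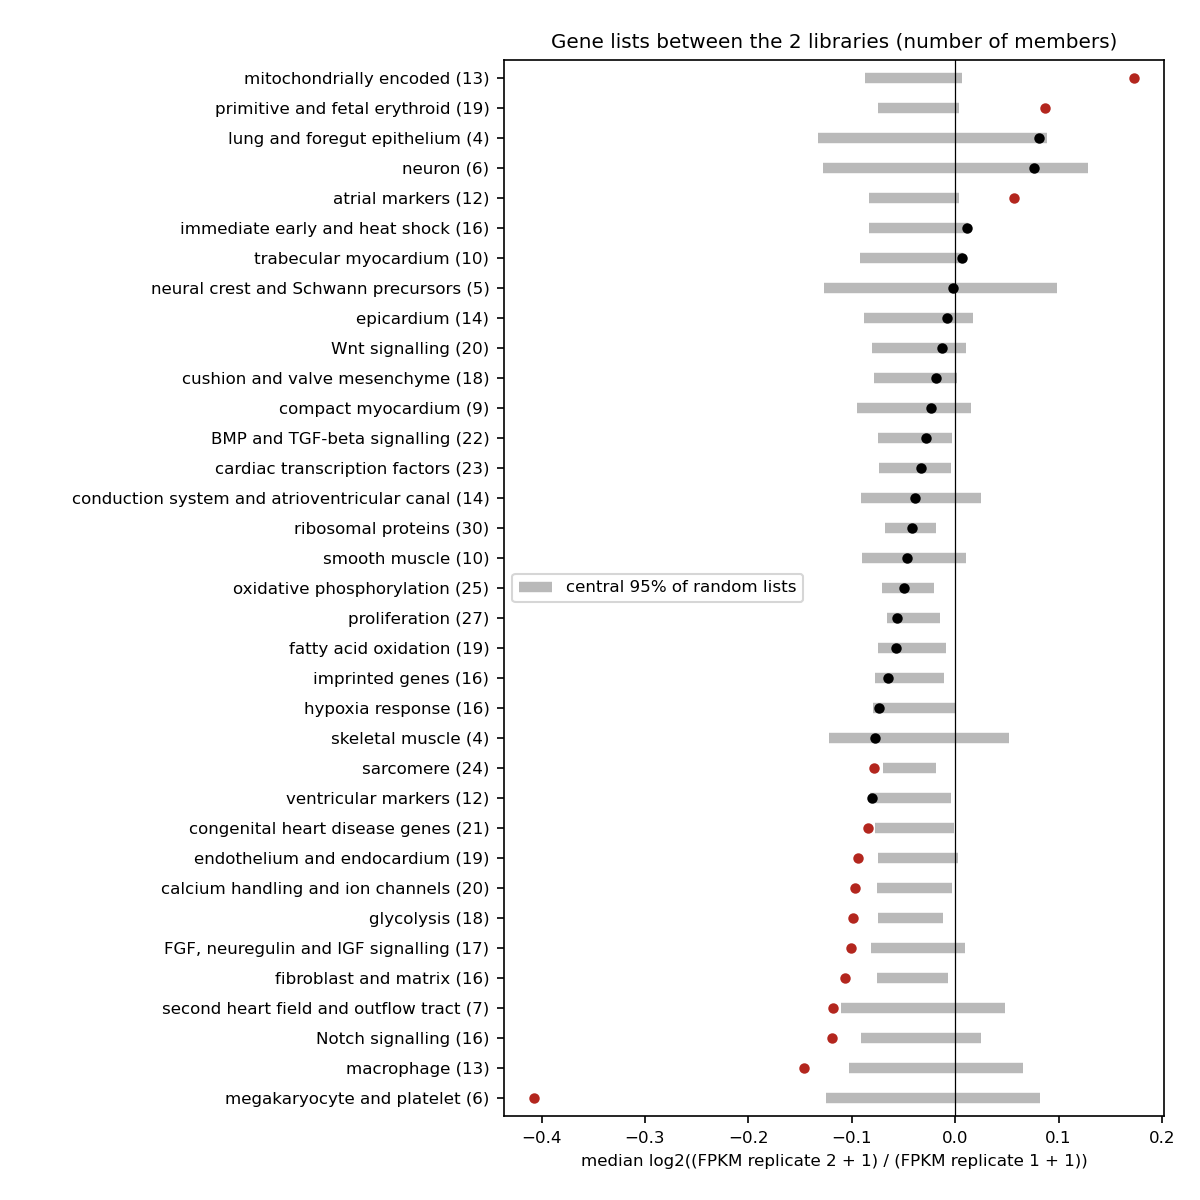
Median log2 difference of replicate 2 over replicate 1 for each list, with the number of members in brackets, over grey bars for the central 95% of random lists matched on expression. Red points lie outside that range, from megakaryocyte genes at -0.41 to mitochondrially encoded genes at 0.17.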

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

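The corrections for length and GC content, the restriction to protein-coding genes not named Gm plus a number, the removal of members at 0 and, for list levels, the highest row of each symbol were chosen after the data were examined. No paired analysis was possible because both samples belong to 1 group. The alternatives gave 555 values for 120 main results, so a result counts once per alternative. Of these values, 508 were labelled unchanged, 24 lost a call, 10 gained one, 12 moved and 1 reversed. Unchanged means on the same side of the threshold or, with no test, inside a tolerance that was wide for counts and narrow for correlations and shares. Counts labelled unchanged include 8754 genes detected in both libraries at 5 FPKM, against 12381 at 1 FPKM. They also include 43 genes differing 2-fold with a pseudocount of 0.1, against 31 in the main result. Except where a value shows it, the cause was not tested.

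Pearson's r was 0.993 with a pseudocount of 0.1 and 0.989 over genes with a mean of 1 FPKM or more, where rho was 0.991. The number of genes differing 2-fold was 93 at a mean of 1 FPKM or more (64 higher in replicate 2), 105 with no filter (75 higher), and 4 among protein-coding genes not named Gm plus a number (3 higher).

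With random lists from genes with a mean of 1 FPKM or more, 15 of the 35 lists run lay above the range and 2 below it. List members under that mean were left out as well. Percentiles that lost the upper call were 96.9 for cardiac transcription factors, 96.7 for atrial, 91.4 for trabecular and 95.9 for compact markers, 53.1 for cushion mesenchyme, 97.41 for smooth muscle, 70.3 for immediate early genes, 97.39 for BMP and 71.8 for FGF signalling. Lung and foregut epithelium rose to 26.45, macrophage genes fell to 0.67 and neuronal genes to 0.33. Skeletal muscle reversed to 97.6, by construction, since only its 4 detected members were left. With each library alone, hepatocyte genes ranged from 0.61 to 2.71 and histones from 1.58 to 4.68. With members at 0 left out, thymus genes lay at 4.165. The ratio of Tbx2 over Tbx3 ranged from 0.31 to 0.56 with each library alone.

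For differences between the libraries, the percentiles after correction for length, and then for length and GC content, were 7.61 and 4.9 for calcium handling, 5.04 and 5.2 for fibroblast and matrix, 4.305 and 4.185 for second heart field, 4.97 and 5.25 for FGF signalling and 7.205 and 4.22 for congenital heart disease, each no longer outside. Newly outside were ventricular markers (0.97 and 0.67), hypoxia response (0.11 and 0.11) and trabecular genes (98.9 and 97.8). With all members above 0 FPKM, ventricular markers lay at 2.11 and immediate early genes at 98.2.

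Without mitochondrially encoded and small RNA genes, the 10 highest genes held 12.1%, the 100 highest 27.7%, erythroid genes 6.99%, sarcomere genes 5.52% and ribosomal protein genes 3.24% of the summed FPKM. Absolute depth is unknown, so it cannot be said how many fragments stand behind a value near 0.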

Other observations

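The patterns below were found in the same 2 libraries on which they were tested, and all are hypotheses. Chosen after the result was seen were the test of an even genomic DNA background, the tests of chance placement and of a strain segment on chromosome 17, and the corrections for length. The general trend with length and the rise of pseudogenes had also been seen before their tests were written. Genes named here outside the naming rule were chosen after their values were seen.

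Genes that are usually abundant were low in both libraries: 7 of the 13 mitochondrially encoded genes lay between 1847 and 9092 FPKM, while mt-Co3 (11.1 FPKM), mt-Atp8 (4.44), mt-Atp6 (3.97), mt-Co2 (3.50), mt-Nd4l (2.89) and mt-Nd3 (1.05) lay far below. Gapdh was at 17.04 FPKM, with 74 other genes matching part of its transcript, 35.7% of which they covered. Rpl37 and Rps6 were at 1.95 and 2.72 FPKM, with 36% and 57.4% covered by copies. A candidate explanation is that reads shared with near-identical copies were lost or given to the copy. Across the 13 mitochondrial genes the share of the transcript covered by a copy and the level had a Spearman rho of -0.644 (permutation p = 0.021). The permutation treats these genes as independent, which genes of 1 genome are not. Against the trend, mt-Atp8 had 0% covered and mt-Nd4 63.6%, but copies outside annotated transcripts were not sought. Across 80 ribosomal protein genes rho was -0.191 (permutation p = 0.0892), which leaves it open whether copies account for their range. The 22 covered for 50% or more had a median of 107 FPKM and ranged from 1.83 to 787 FPKM. The 58 covered for less had a median of 137 FPKM and ranged from 0 to 964 FPKM. No biological explanation was tested here or for the pseudogenes.

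Pseudogenes were higher in replicate 2. Of 166 with a mean of 5 FPKM or more, 136 were higher there (81.9%), against 28.0% of protein-coding genes, with a median ratio of 1.37. The rise was not larger in pseudogenes with near-identical copies. The 103 covered for 50% or more by a copy rose too, with a median log2 difference of 0.461. That median was 0.23 lower than in the others searched (-0.231, permutation p = 0.0159). The permutation treats pseudogenes as independent, although related ones can share reads. Copies of lower identity or outside annotated transcripts were not sought, so the split cannot separate shared reads from other causes. The 44 pseudogenes covered for less had a median log2 difference of 0.69 (0.692, bootstrap interval 0.406 to 0.851). This met the criterion written beforehand for genomic DNA or unspliced RNA in replicate 2. It would also follow from any cause other than near-identical copies, so this test leaves both open. A further test, chosen after that outcome, argues against an even background of genomic DNA. Among 1757 olfactory and vomeronasal receptor genes the highest value in replicate 2 was 0.676 FPKM. That is under the median gain of 3.27 FPKM of the pseudogenes (bootstrap interval 2.35 to 4.17). Unspliced RNA and reads shared with copies, near-identical or of lower identity, may still contribute.

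Across 8611 genes, which are not independent, transcript length and the log2 difference between the libraries had a Spearman rho of -0.257. Of the 11 lists lower in replicate 2, 5 came inside the random range after subtraction of that trend and 6 stayed below it.

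Genes that differed between the libraries clustered on chromosome 17: among 8519 protein-coding genes, without ribosomal protein genes (Rps18 lies in the window), mitochondrial genes and those named Gm plus a number, 193 stood more than 3 half-widths from the median of genes at their level, and 12 of the 95 in the window from 30 to 40 Mb (mm9) did, where 2.15 are expected. The exact hypergeometric test of that window gave p = 1.37e-06 and a Benjamini-Hochberg adjusted p of 0.000373 over 272 windows of the 1 size tried. Btbd9 was at 11.2 FPKM in replicate 1 and 23.4 in replicate 2, Glo1 at 50.6 and 93.1, and H2-D1 at 15.2 and 6.62. The other outlying genes of the window differed less, in size from 0.17 log2 units for Zfp414 to 0.41 for H2-Ke6. In all, 8 genes were higher in replicate 2 and 4 in replicate 1, between 30352469 and 35404444. Chance placement is argued against by 2000 shuffles (permutation p = 0.0005, the smallest they can give). The length trend is argued against by 10 of the 11 genes with a known length still standing out after correction. Of 11 searched genes, 1 was covered for 50% or more by near-identical copies, which argues against such copies within annotated transcripts only. Copies of lower identity or outside annotated transcripts were not sought, so reads shared with them may still contribute. A chromosome segment that differed between the sampled embryos in the mixed strain background may be the source and cannot be told apart from other causes, since genotypes were not analysed here, and the 0 other windows that passed do not bear on it.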
